A study of Homo sapiens with 5 samples.

How the data were processed

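RNA from 22Rv1 cells was sequenced in 5 libraries, Vector-1, ESM1, Vector-2, ESM1-NLS and ESM1-NES, with 1 library in each group. Groups were taken from the sample titles and the pairing of each form with its vector from the design text. Reads were processed with Trimmomatic, Bowtie2 and RSEM on hg19, per the submitters' processing notes, which name no versions and no order. The kit's strandedness is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner may not be separable. The authors deposited 2 tables with the same 26506 gene symbols and no coordinates.

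The table with Vector-1 and ESM1 carries no unit in its header. Its values were taken as FPKM because the deposited columns do not share 1 total, as TPM would, and because most low values lie near whole multiples of the step that 1 read makes for the same gene in the other table. That reading comes from the values, not from a label. The table with Vector-2, ESM1-NLS and ESM1-NES holds expected counts, TPM and FPKM, per the file headers. It also holds a fold change for each tagged form over the vector and a score named PPEE, both made by the authors. PPEE is the name that EBSeq gives to a posterior probability of equal expression, it is not a p-value, and the tool behind it is not given in the sources used here. The authors' fold change and score were used only where the text names the authors' deposited table.

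Depth was the sum of expected counts for the second table. For the first table it was estimated by searching for the factor at which low values came nearest to whole reads. At that factor 86.0% of 129 values in ESM1 and 86.6% of 127 values in Vector-1 lay within 0.15 reads of a whole number. The same search with the steps shuffled among genes, added after the data were seen, gave at most 75.0% and 72.2% in 200 shuffles for each library. Reads per gene in those libraries are therefore estimates. Ratios of FPKM carry exact 95% conditional binomial intervals (Clopper-Pearson) on the reads, which cover counting error only. Expected counts were rounded to whole numbers for these intervals, and between 82.0% and 84.6% of those above 0 were within 0.005 of a whole number to begin with. A gene at 0 in a vector was set against a floor of 3 reads per library.

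The measure of each comparison was the difference of log2(FPKM + 1) between 2 libraries, which understates the change of low genes. FPKM was used in both tables so that unit and pseudocount were the same. A gene was counted when its mean over the 2 libraries was 1 FPKM or more and the difference was at least 2-fold. No test across samples exists with 1 library per group. Each comparison was made within 1 table, except that of the vectors and the alternative with Vector-2 as control of ESM1, which cross tables that were normalised separately.

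There were 27 gene lists, written before the data were examined, as were the measure of each comparison, the main alternatives and the rule for named genes. For each list with 5 or more measured members the median difference was placed among the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. A list was said to stand apart when it lay in the outermost 2.5% at either end, which describes these libraries and is not a test. A second matching used 5 bins of expression, 4 of length and 4 of GC content. ESM1 was left out of the lists' background. In simulated libraries with counting noise, between 2 and 4 of 100 unchanged lists stood apart per comparison. Genes simulated with a 4-fold change were recovered at 95% in ESM1, 98% in ESM1-NLS, 95% in ESM1-NES and 89% in ESM1-NLS against ESM1-NES, each of 100 genes, and 2.5-fold changes at 81%, 82%, 85% and 81%, among 12961, 12977, 12972 and 12970 genes.

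Genes were named by a rule. ESM1 came first, then CTNNB1, AXIN2, LEF1, MYC, CCND1, CD44, KLK3, SOX2, POU5F1, NANOG and KLF4. Next came the 8 genes with the largest positive and the 8 with the largest negative difference among official symbols, and up to 4 members of each list with the largest absolute difference. Genes named outside that rule are said to have been chosen after their values were seen. Some genes and 1 list covered by the rule and the list counts are not reported here. Y-linked genes were left out of named genes and of the protein-coding set.

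Gene symbols were matched to RefSeq genes of GRCh38.p14 for names and biotypes, and 25328 matched. The build differs from hg19, so no coordinates are given. Effective length was derived from the authors' FPKM and expected counts, and GC content from reference transcripts of the newer build, with a value for at least 97.3% of the genes used. None of the 13 mitochondrially encoded genes on a list carried its symbol in the tables, so that list has 0 measured members. Markers of other cell types were looked at in 4 lists, of endothelial, fibroblast and smooth muscle, leukocyte and kidney packaging cells.

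Alternatives were a pseudocount of 0.1 or 5, no filter on low values, a mean of 5 or more, rescaling to a median difference of 0 or by TMM factors from edgeR, thresholds of 1.5-fold and 3-fold, official symbols alone, the mean of a list and random lists without matching. Added after the data were seen were TPM, protein-coding genes without a hyphen in the symbol and with a mean of 5 or more, subtraction of the median of each of 10 length by 10 GC bins, the second matching and Vector-2 as control of ESM1. TPM of the first table was made from its FPKM. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.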

Results

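The data are RNA sequencing of total RNA from 22Rv1, an established human prostate carcinoma cell line, collected 72 hours after lentivirus was added to cells in medium with 10% serum. ESM1 encodes a proteoglycan, also called endocan, that carries a signal peptide for secretion. There are 5 libraries, 1 in each group. Vector-1 is the control of cells given ESM1. Vector-2 is the control of cells given ESM1-NLS and of cells given ESM1-NES. NLS and NES are the usual abbreviations of nuclear localisation signal and nuclear export signal, and the labels do not spell them out. The series title relates nuclear ESM1 to stemness and to β-catenin signalling, so the Wnt pathway and stemness genes were examined first. Expected counts summed to 24322216 reads in Vector-2, 19975113 in ESM1-NLS and 18447256 in ESM1-NES. For the other table, which holds FPKM alone, the depth estimated from the steps of its low values was 15315261 reads in Vector-1 and 13839627 in ESM1. With 1 library per group no difference has a replicate check, and no p-value is given. Intervals in parentheses after a ratio of FPKM values are exact 95% intervals (Clopper-Pearson) that cover counting error only.

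ESM1 itself matched the labels in each library. It was listed at 0 FPKM in both vector libraries and at 2437 FPKM in ESM1, 2627 FPKM in ESM1-NLS and 3431 FPKM in ESM1-NES. Against a floor of 3 reads per vector library, these levels were at least 25119-fold, 43011-fold and 56176-fold higher. The transgene took 0.496%, 0.530% and 0.691% of the reads. Its level in ESM1-NES was 1.31 times that in ESM1-NLS (1.30 to 1.32).

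**Figure D1:**
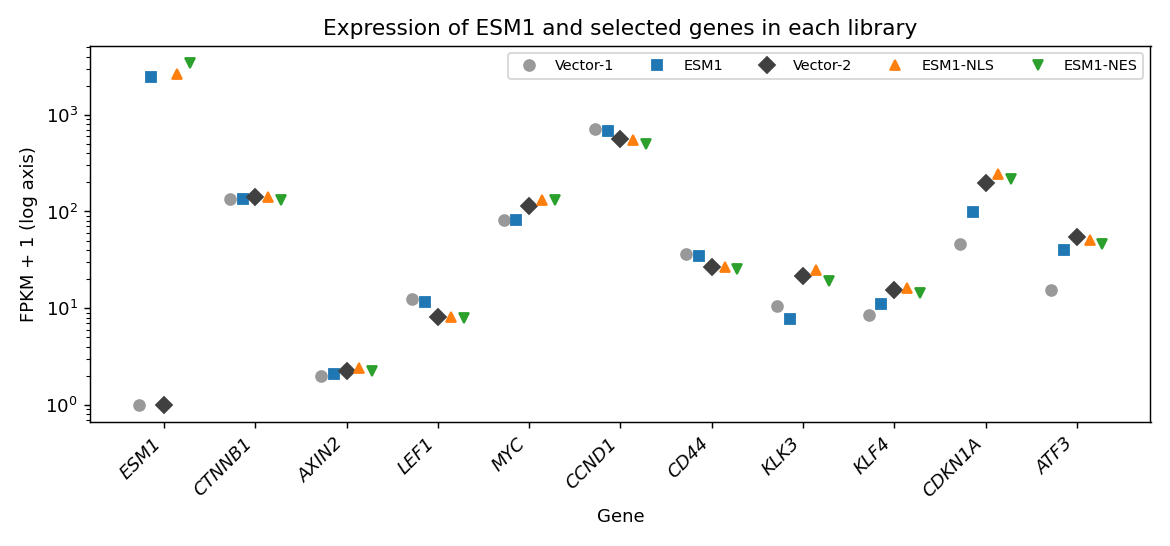
FPKM + 1 on a log axis for ESM1 and selected genes, with 1 point per library. ESM1 reaches 2437 to 3431 FPKM in the libraries given a form of it and 0 in the vectors, CTNNB1 lies between 129 and 141 FPKM in all 5 libraries, and CDKN1A and ATF3 are lower in Vector-1 than in the other libraries.

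ESM1 against Vector-1 asks what the protein without an added localisation signal does to the transcriptome. Targets of p53, the stress-activated transcription factor, were higher in ESM1, with a median log2 difference of 0.59, and all 20 measured members lay above 0. CDKN1A, which encodes the cell cycle inhibitor p21, was at 97.2 FPKM against 45.6 FPKM, 2.13 times as high (2.0 to 2.27). Genes of the unfolded protein response and ATF4 targets were higher too, with a median of 0.33 and 24 of 25 members above 0. ATF3, a stress-induced transcription factor, was 2.69 times as high (2.40 to 3.01), and HSPA5, the main chaperone of the endoplasmic reticulum, was 1.93 times as high (1.88 to 1.98). Against Vector-2, the vector of the other experiment and table, both lists lay the other way in ESM1, at -0.26 for p53 targets and -0.06 for the unfolded protein response and ATF4 targets. Wnt target genes and stemness genes did not stand apart from random lists.

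Among p53 targets, 10 of 20 were at least 1.5-fold higher and 0 were 1.5-fold lower. PHLDA3, an inhibitor of AKT, was 2.32 times as high, BBC3, which encodes the pro-apoptotic protein PUMA, 2.09 times, and DDB2, a DNA damage binding protein, 1.87 times. In the unfolded protein response and ATF4 list, 6 of 25 were at least 1.5-fold higher, among them CHAC1 at 2.87 times and HERPUD1 at 2.16 times. Immediate early genes had a median of 0.28, with 15 of 18 above 0, and JUN was 1.67 times as high and KLF6 1.56 times. ATF3 belongs to both of these lists. Histone genes had a median of 0.52 with 9 of 10 above 0. HIST1H2AC was 2.80 times as high (1.43 to 5.80) and HIST1H2BK 1.62 times, and histone copies are near-identical, so the division of reads among them is uncertain. Genes of cholesterol synthesis had a median of 0.19 with 20 of 20 above 0, and MVD, of the mevalonate pathway, was 1.59 times as high.

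Proliferation genes were lower in ESM1, with a median of -0.10 and 28 of 31 below 0. MKI67, which encodes the Ki-67 antigen, was at 0.676 of its Vector-1 level (0.646 to 0.708), NUSAP1 at 0.785 and CENPF at 0.801. KLK3, which encodes prostate-specific antigen, was at 0.716 of its Vector-1 level (0.573 to 0.892). Luminal epithelial genes, with a median of 0.10, and cytosolic ribosomal protein genes, with a median of 0.06, also stood apart in the matching on expression, and neither did once random lists were matched on length and GC content as well.

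CTNNB1, which encodes β-catenin, was at 133.8 FPKM in ESM1 and 132.5 FPKM in Vector-1, a ratio of 1.01 (0.976 to 1.04). AXIN2, a direct target of Wnt signalling, had a ratio of 1.09 (0.756 to 1.57), LEF1 0.909 (0.805 to 1.03), MYC 0.990 (0.938 to 1.05) and CCND1, which encodes cyclin D1, 0.961 (0.949 to 0.975). Wnt target genes had a median of -0.05, at percentile 6.05 of the random lists, and Wnt pathway components one of -0.01, at percentile 29.9. Stemness genes had a median of 0.00, with 7 of 14 above 0. CD44 had a ratio of 0.969, KLF4 one of 1.36 (1.17 to 1.58) and ABCG2, a drug efflux pump, one of 0.668. SOX2 at 0.60 against 0.87 FPKM and POU5F1 at 1.18 against 0.94 FPKM were too low for this depth to separate the libraries, and NANOG was at 0.07 FPKM or less in both.

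Among 12296 genes with a mean of 1 FPKM or more, 33 were at least 2-fold higher and 2 at least 2-fold lower in ESM1. In libraries simulated without any difference between the remaining genes, 7 unchanged genes passed this limit. Most of the genes at the extremes were small RNAs or copies. NUDT4P1, a near-identical copy of NUDT4, was at 7.65 against 0.50 FPKM, and SNORA50C, SNORD104, RNU86, SNORD35B and SNAR-G1 were listed at 0 in Vector-1. At the lower end were NBL1 at 0.31 against 3.09 FPKM and the readthrough locus SEPT5-GP1BB at 0.05 against 2.13 FPKM, both of which overlap other genes. Among 8606 protein-coding genes with a mean of 5 FPKM or more, an alternative chosen after the values were seen, 5 were 2-fold higher and 0 were lower. Apart from ESM1 these were ATF3, PHLDA3, HERPUD1 and CDKN1A. PEG10, an imprinted gene derived from a retrotransposon and also chosen after its values were seen, was the lowest of that set at 0.584 of its Vector-1 level.

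Among the lists that did not stand apart in ESM1, mesenchymal genes had a median of -0.10, basal epithelial genes 0.08, neuroendocrine genes 0.09, interferon-stimulated genes 0.03, NF-kB targets 0.07, hypoxia and glycolysis genes -0.04, angiogenic factors 0.01, Notch pathway genes -0.01, oxidative phosphorylation genes -0.03 and housekeeping genes 0.03. In all, 9 of 23 lists stood apart, against 1.15 for random lists, whose genes need not vary together. Between Vector-1 and Vector-2, in separate experiments and tables, 10 of 23 lists stood apart. Mesenchymal genes lay at the limit when random lists were matched on length and GC content as well, at percentile 2.085 in one draw of random lists, past it, and 2.515 in another, within it. Against Vector-2 proliferation genes had a median of 0.34 in ESM1, immediate early genes one of -0.28 and cytosolic ribosomal protein genes one of -0.29, opposite to their directions against Vector-1.

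ESM1-NLS against Vector-2 asks what the form with the NLS does. Few genes differed: 10 of 13000 were at least 2-fold higher and 6 at least 2-fold lower, and 5 unchanged genes passed the limit in simulated libraries. At 1.5-fold the split turned, to 48 higher and 65 lower. Hypoxia and glycolysis genes were lower, with a median log2 difference of -0.23 and 16 of 21 below 0. BNIP3, a mitophagy receptor induced by HIF-1, was at 39.8 against 66.3 FPKM, a ratio of 0.599 (0.559 to 0.642). Vector-1 and ESM1, across tables, were also lower than Vector-2 in this list, with medians of -0.32 and -0.36, so the difference may belong to the single Vector-2 library. Proliferation genes were lower as well, with a median of -0.14 and 26 of 31 below 0. Neither Wnt target genes nor stemness genes stood apart.

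In the hypoxia list ANKRD37 had a ratio of 0.427 (0.267 to 0.664), PFKFB3, which encodes a regulator of glycolysis, 0.691 and PFKFB4 0.725. Among proliferation genes MKI67 had a ratio of 0.534 (0.510 to 0.559), CENPF 0.607, CENPE 0.727 and TOP2A 0.787. MKI67, CENPF and CENPE have effective lengths of 11916, 10251 and 8343 bases, and 91.4% of protein-coding genes over 8000 bases were lower in ESM1-NLS. Cholesterol synthesis genes had a median of -0.14 with 16 of 20 below 0, and INSIG1, a sterol-responsive regulator, had a ratio of 0.652 (0.602 to 0.706). Oxidative phosphorylation genes had a median of -0.12 with 28 of 32 below 0, with UQCRQ at a ratio of 0.744. p53 targets had a median of 0.17 with 17 of 21 above 0, but 0 of them reached 1.5-fold. GDF15 had a ratio of 1.37, PHLDA3 1.28 and CDKN1A 1.25 (1.22 to 1.29).

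CTNNB1 was at 141.2 FPKM in ESM1-NLS and 139.4 FPKM in Vector-2, a ratio of 1.01 (0.986 to 1.04). AXIN2 had a ratio of 1.11 (0.857 to 1.44), LEF1 1.01, MYC 1.14 (1.10 to 1.18), CCND1 0.989 and CD44 0.978. Wnt target genes had a median of 0.04, Wnt pathway components 0.04 and stemness genes -0.03. Within those lists DKK1, a secreted Wnt antagonist that Wnt signalling induces, had a ratio of 1.34 (1.11 to 1.62), ALDH1A1 1.21 and BMI1, a Polycomb protein, 0.825. SOX2 had a ratio of 1.08 (0.730 to 1.60), POU5F1 0.805 (0.570 to 1.13) and KLF4 1.06 (0.965 to 1.16), and NANOG was at 0.10 FPKM. KLK3 had a ratio of 1.18 (1.06 to 1.31).

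SMN2 was listed at 0 in ESM1-NLS against 12.8 FPKM in Vector-2 and BAGE5 at 0 against 2.91 FPKM, whereas BAGE4 was at 2.70 against 0.11 FPKM. Each has a near-identical copy, so these values are uncertain. MTRNR2L2 and MTRNR2L8, nuclear copies of a mitochondrial ribosomal RNA segment, were 2.09 and 2.07 times as high, and reads of the mitochondrial transcript can be assigned to them. AHNAK, a very long transcript, was at 0.495 of its Vector-2 level (0.483 to 0.508). Among 9034 protein-coding genes with a mean of 5 FPKM or more, 1 was 2-fold higher, ESM1, and 1 lower, SMN2.

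Luminal epithelial genes had a median of 0.12 and immediate early genes one of 0.15, and both stopped standing apart when random lists were matched on length and GC content. The lists that did not stand apart included mesenchymal genes at 0.12, basal epithelial genes at 0.09, neuroendocrine genes at 0.07, interferon-stimulated genes at 0.04, NF-kB targets at 0.05, unfolded protein response and ATF4 targets at 0.00, angiogenic factors at 0.04, Notch pathway genes at 0.01, histone genes at 0.07, cytosolic ribosomal protein genes at -0.04 and housekeeping genes at -0.01. In all, 7 of 23 lists stood apart.

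ESM1-NES against Vector-2 asks what the form with the NES does. The hypoxia and glycolysis list was lower, with a median log2 difference of -0.26 and 16 of 21 members below 0, and BNIP3 had a ratio of 0.646 (0.603 to 0.691). It rests on the same Vector-2 library, which was higher in this list than each of the other 4 libraries. ANKRD37 had a ratio of 0.448 (0.278 to 0.700). All 57 cytosolic ribosomal protein genes lay above 0, with a median of 0.22. The difference from Vector-2 also followed gene length. Protein-coding genes over 8000 bases had a median of -0.42 with 96.7% of them lower, and those of up to 1000 bases a median of 0.20.

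Across 8882 protein-coding genes the Spearman rho between effective length and the log2 difference was -0.63 in ESM1-NES, -0.16 in ESM1-NLS and -0.31 in ESM1, on the genes of each comparison, which are not independent replicates. With GC content of the transcripts it was 0.69, 0.60 and 0.38. In ESM1-NLS genes over 8000 bases had a median of -0.18, and in ESM1 one of -0.11.

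**Figure D2:**
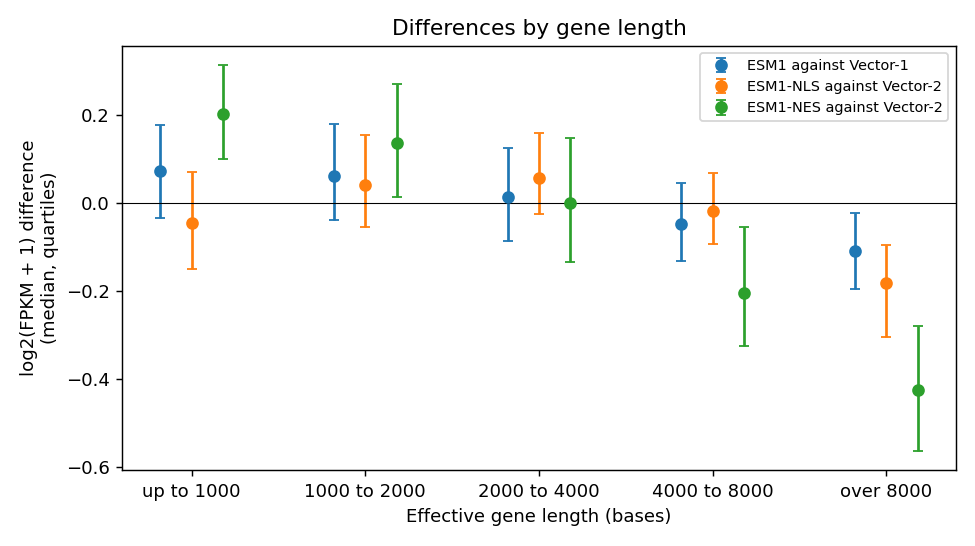
Median log2(FPKM + 1) difference from the vector library, with bars from the lower to the upper quartile of genes, by effective gene length in bases, for protein-coding genes with a mean of 5 FPKM or more. In ESM1-NES the median goes from 0.20 for genes of up to 1000 bases to -0.42 for genes over 8000 bases.

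In the hypoxia list NDRG1 had a ratio of 0.676 and the histone demethylase gene KDM3A 0.672. KLK3 had a ratio of 0.895 (0.796 to 1.01). The ribosomal protein list lay at percentile 97.52 of lists matched on expression, barely past the limit. It no longer stood apart with a pseudocount of 0.1, at percentile 97.16, or with a mean of 5 or more, at 97.275. Lists matched on length and GC content as well spanned 0.12 to 0.21 in their central 95%. RPL28 had a ratio of 1.31. With TPM, where the median of all genes lies -0.12 from its FPKM value, the ribosomal protein median was 0.10.

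CTNNB1 was at 129.4 FPKM in ESM1-NES against 139.4 FPKM in Vector-2, a ratio of 0.928 (0.902 to 0.955). AXIN2 had a ratio of 0.976 (0.739 to 1.28), LEF1 0.986, MYC 1.14 (1.10 to 1.18), CCND1 0.880 and CD44 0.943. Wnt target genes had a median of 0.05 and Wnt pathway components 0.02. LRP6, a Wnt co-receptor with a long transcript, had a ratio of 0.599 (0.552 to 0.650) and APC 0.664. Stemness genes had a median of -0.10 with 12 of 15 below 0, at percentile 22.4 of the random lists. With random lists matched on length and GC content as well they lay at percentile 63.5. BMI1 had a ratio of 0.628 (0.567 to 0.695). POU5F1 was at 1.26 against 1.95 FPKM, a ratio of 0.646 (0.440 to 0.936). SOX2 had a ratio of 0.808 (0.519 to 1.24) and KLF4 0.932 (0.844 to 1.03), and NANOG was at 0.11 FPKM.

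Of 12902 genes, 9 were at least 2-fold higher and 20 at least 2-fold lower in ESM1-NES, and 9 unchanged genes passed the limit in simulated libraries. The lean to lower genes was larger at 1.5-fold, with 50 higher and 279 lower. It was also larger with TPM, with 20 and 70, and with a pseudocount of 0.1, with 18 and 73. Without a filter it was smaller, with 15 and 29, and a pseudocount of 5 left 1 and 1. ADORA2A was at 3.39 against 0.76 FPKM and its readthrough locus SPECC1L-ADORA2A at 0.18 against 2.40 FPKM, which share exons. SMN2, BAGE5, SNORA109, SNORA4 and the readthrough locus EEF1E1-BLOC1S5 were listed at 0 in ESM1-NES. Among 8883 protein-coding genes with a mean of 5 FPKM or more, 1 was 2-fold higher, ESM1, and 4 were lower. These were SMN2 and, chosen after their values were seen, SFT2D2 with a ratio of 0.336 (0.244 to 0.456), PANK3 with 0.472 and ZNF121 with 0.448.

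Among the lists that did not stand apart in ESM1-NES in the matching on expression, luminal epithelial genes had a median of 0.07, mesenchymal genes 0.10, basal epithelial genes 0.00, neuroendocrine genes -0.04, proliferation genes -0.01, interferon-stimulated genes 0.06 and NF-kB targets 0.06. Unfolded protein response and ATF4 targets had a median of 0.09, p53 targets -0.03, cholesterol synthesis genes 0.01, immediate early genes -0.03, angiogenic factors 0.01, Notch pathway genes -0.03, histone genes -0.09, oxidative phosphorylation genes 0.13 and housekeeping genes 0.07. With random lists matched on length and GC content as well, luminal epithelial, immediate early and histone genes stood apart at the lower end, at percentiles 1.90, 2.02 and 1.39, and 5 of 23 lists stood apart against 3 before.

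**Figure D3:**
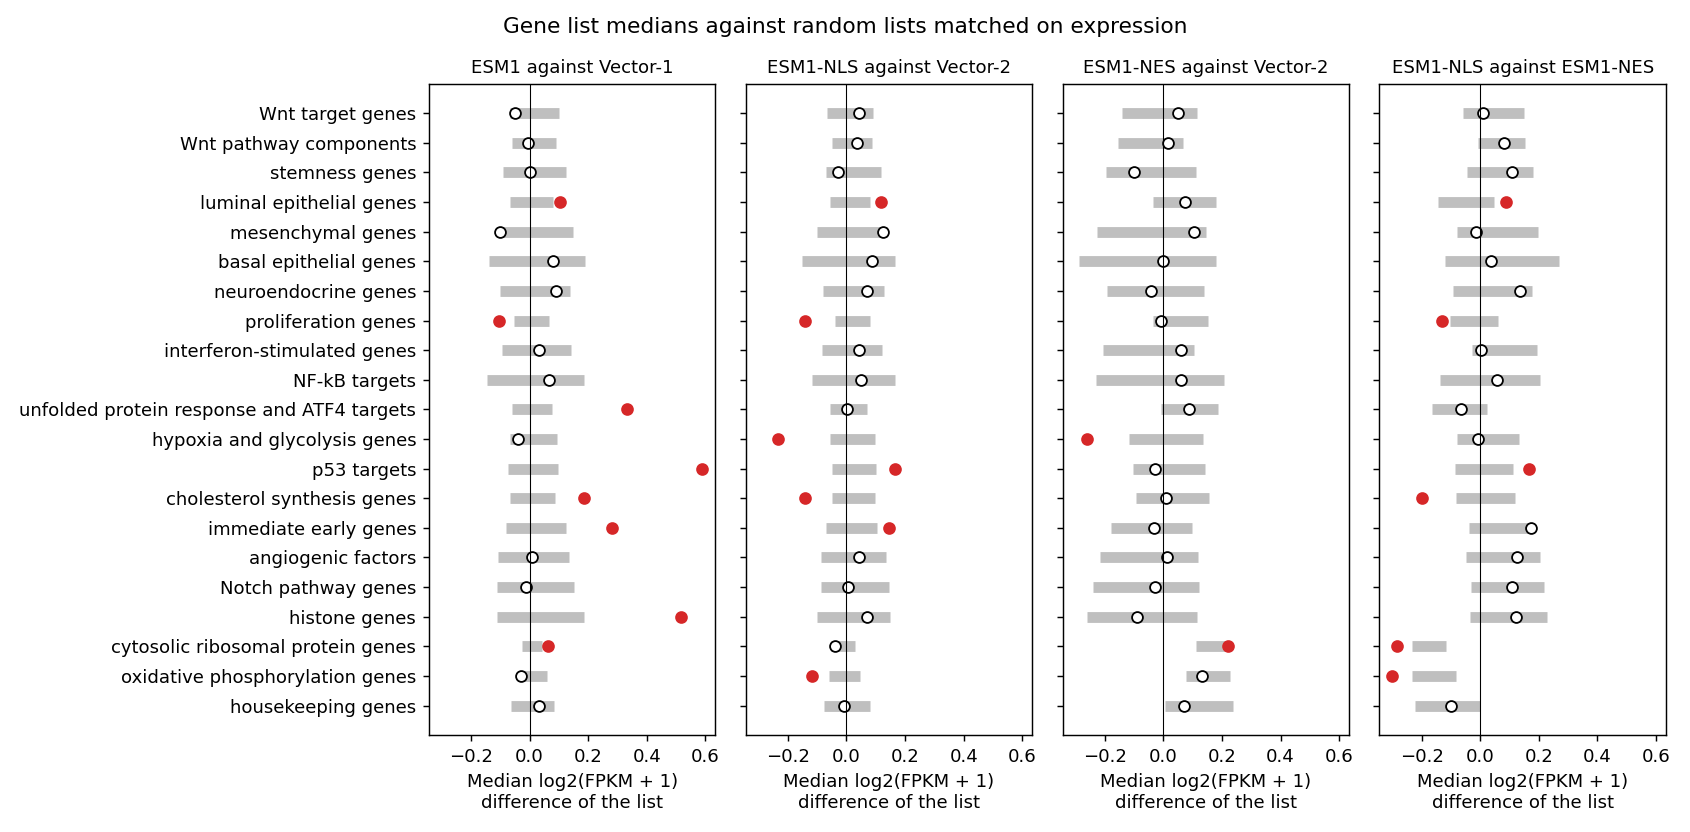
Median log2(FPKM + 1) difference of each gene list reported here and measured with 5 or more members, 1 panel per comparison. Grey bars span the central 95% of 10000 random lists matched on expression, filled red points stand outside that span, and open points within it. p53 targets reach 0.59 in ESM1, and hypoxia and glycolysis genes -0.23 and -0.26 in ESM1-NLS and ESM1-NES.

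ESM1-NLS against ESM1-NES compares the tagged forms directly, with both libraries in 1 table. p53 targets were higher in ESM1-NLS, with a median log2 difference of 0.17 and 18 of 21 above 0. TP53INP1 was 1.61 times as high (1.52 to 1.70). Its effective length is 5573 bases, and protein-coding genes of 4000 to 8000 bases had a median of 0.18 in this comparison. Among random lists drawn without matching, the p53 list no longer stood apart, at percentile 97.24. KLK3 was 1.32 times as high (1.17 to 1.48). Oxidative phosphorylation genes were lower in ESM1-NLS, with a median of -0.30 and 30 of 32 below 0, and so were cytosolic ribosomal protein genes, with a median of -0.28 and 57 of 57 below 0. This difference followed gene length too. Across 8896 protein-coding genes the rho between effective length and this difference was 0.68, and genes of up to 1000 bases had a median of -0.25 with 93.8% of them lower. The oxidative phosphorylation and ribosomal protein lists have median lengths of 741 and 654 bases. The central 95% of random lists matched on expression, length and GC content spanned -0.21 to -0.09 and -0.23 to -0.14, and both lists lay below it. That matching used only 4 bins of length, so a trend within the shortest bin may remain. It therefore does not separate these lists from the trend with length. Cholesterol synthesis genes had a median of -0.20 with 19 of 20 below 0, and INSIG1 had a ratio of 0.709.

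COX7A2 had a ratio of 0.707 and COX6A1 0.712 among the oxidative phosphorylation genes, and RPL24 0.746 among the ribosomal proteins. Proliferation genes had a median of -0.13 with 28 of 31 below 0, CDC20 with a ratio of 0.775 and AURKB with 0.802. With TPM, which moves the median gene by 0.13, the median of the list was 0.00. Luminal epithelial genes had a median of 0.09. CTNNB1 was 1.09 times as high in ESM1-NLS (1.06 to 1.12) and AXIN2 1.14 times (0.861 to 1.51). LEF1 was 1.02 times as high, CCND1 1.12 times and CD44 1.04 times, and MYC had a ratio of 0.995. Rescaling to a median difference of 0 gave log2 differences of 0.078 for CTNNB1 and 0.123 for CCND1, outside their counting intervals. Differences of this size therefore depend on the scaling. Wnt target genes, with a median of 0.01, Wnt pathway components, with 0.08, and stemness genes, with 0.11, did not stand apart. SOX2 had a ratio of 1.34 (0.858 to 2.11), POU5F1 1.25 (0.833 to 1.88) and KLF4 1.14 (1.03 to 1.26), and NANOG was near the floor in both.

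Of 12915 genes, 7 were at least 2-fold higher and 11 at least 2-fold lower in ESM1-NLS. With TPM the split was 53 higher and 19 lower, and with the median of each length and GC bin subtracted it was 17 higher and 7 lower, while rescaling to a median of 0 or by TMM gave 6 higher and 13 lower. A pseudocount of 0.1 gave 38 higher and 26 lower, no filter 27 and 16, and a limit of 1.5-fold 100 and 46, so the direction of the split depends on the processing. None of 8897 protein-coding genes with a mean of 5 FPKM or more differed 2-fold. Readthrough loci and copies again held the extremes, among them EEF1E1-BLOC1S5 at 2.29 against 0 FPKM and GAGE6 at 0 against 2.57 FPKM. Immediate early genes at 0.17 and histone genes at 0.12 stood apart when random lists were matched on length and GC content as well, at percentiles 99.93 and 97.67, and not in the matching on expression, so that 9 of 23 lists stood apart against 7 before. The lists that did not stand apart also included hypoxia and glycolysis genes at -0.01, unfolded protein response and ATF4 targets at -0.07, mesenchymal genes at -0.01, basal epithelial genes at 0.04, neuroendocrine genes at 0.13, interferon-stimulated genes at 0.00, NF-kB targets at 0.06, angiogenic factors at 0.12, Notch pathway genes at 0.11 and housekeeping genes at -0.10.

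The agreement of the comparisons was measured across genes without ESM1. Differences in ESM1 correlated with those in ESM1-NLS with a Pearson r of 0.213 and a Spearman rho of 0.269, and with those in ESM1-NES with an r of 0.293 and a rho of 0.345. These pairs share no library. With the median of each length and GC bin subtracted, r was 0.0807 and 0.0747. Of genes at least 1.5-fold higher, ESM1 shared 4 with ESM1-NLS, against 0.276 for independent lists, and 5 with ESM1-NES, against 0.364. BAGE4, whose values are uncertain, is among the genes shared with each. Of genes at least 1.5-fold lower ESM1 shared 0 with ESM1-NLS, against 0.161, and 4 with ESM1-NES, against 0.773. No simulation was run for these pairs. ESM1-NLS and ESM1-NES correlated with an r of 0.599 and a rho of 0.580, and share Vector-2. Simulated unchanged libraries with counting noise alone gave 0.441, and noise of the size of the difference between the tagged forms gave 0.502. The covariance was 0.0280 against 0.00387 and 0.0190 in those simulations. The tagged forms shared 11 genes at least 1.5-fold higher and 31 lower. The same simulations, which keep the shared vector, gave at most 7 and 6 with counting noise and 8 and 9 with the larger noise, drawn from a normal distribution. The larger noise was set to the same size in Vector-2 as in the tagged forms. Vector-2 is 1 library and cannot be divided, so part or all of the excess may come from it. In all 3 comparisons with a vector, 2 genes were at least 2-fold higher, ESM1 and BAGE4, and 0 were 2-fold lower. BAGE4 has a near-identical copy, BAGE5, so its values are uncertain.

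The vector libraries differed far more from each other than any overexpression library did from its own control. Of 12685 genes, 137 were at least 2-fold higher and 465 at least 2-fold lower in Vector-1 than in Vector-2. They belong to separate experiments and separately normalised tables. Cholesterol synthesis genes had a median log2 difference of 0.57 and proliferation genes one of 0.44 in Vector-1, whereas p53 targets had one of -0.68 with 19 of 20 below 0, unfolded protein response and ATF4 targets one of -0.30 and hypoxia and glycolysis genes one of -0.32 with 18 of 21 below 0. Wnt target genes had a median of 0.11 in Vector-1 over Vector-2, with 13 above 0 and 10 below, and stood apart at percentile 99.03. Stemness genes had one of 0.13, at percentile 97.03, and did not stand apart. The genes named next were chosen after their values were seen. CYP1A1, a target of the aryl hydrocarbon receptor, was at 44.6 FPKM in Vector-1 and 4.21 FPKM in Vector-2, HMGCS1, of cholesterol synthesis, at 109 and 25.9 FPKM, and DKK1 at 29.6 and 5.05 FPKM. CDKN1A was at 45.6 FPKM in Vector-1 and 196 FPKM in Vector-2, HES7 at 2.36 and 20.1 FPKM, and DDIT4 at 30.1 and 117 FPKM. Of all genes with a mean of 1 FPKM or more, 80.8% lay within 1.5-fold between the vectors, against 98.5% for ESM1 and 99.1% for ESM1-NLS with their own vectors.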

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

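Values in opposite directions between 2 of the comparisons with a vector drew attention here, and neither difference was tested. The search first covered gene lists in ESM1-NLS and ESM1-NES alone and found none, and it was widened to ESM1 and to single named genes after the values had been seen. Cholesterol synthesis genes stood apart upward in ESM1, with a median log2 difference of 0.19, and downward in ESM1-NLS, with one of -0.14, each against its own vector. SNORA50C, a small nucleolar RNA, had a log2 difference of 2.501 in ESM1, from a value of 0 in Vector-1. That value rests on an estimated 4.59 reads in ESM1, so it is near the floor. In ESM1-NLS SNORA50C had a log2 difference of -1.04, where the ratio of 0.359 had a counting interval from 0.0364 to 1.89.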

How the results depend on the processing

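Counts of genes differing 2-fold stayed within 1.5 times their main value after rescaling to a median of 0, by TMM, with official symbols alone and with length and GC bins subtracted, and moved otherwise. In the order ESM1, ESM1-NLS, ESM1-NES, and ESM1-NLS against ESM1-NES, the main counts of 35, 16, 29 and 18 became 84, 55, 91 and 64 with a pseudocount of 0.1, 6, 5, 2 and 0 with one of 5, 55, 42, 44 and 43 without a filter, and 7, 6, 8 and 0 with a mean of 5 or more. They were 186, 113, 329 and 146 at 1.5-fold and 16, 7, 11 and 7 at 3-fold. Among alternatives chosen after seeing the data they were 82, 58, 90 and 72 with TPM and 5, 2, 5 and 0 in protein-coding genes with a mean of 5 or more. Thresholds, filters and pseudocounts change the counts by their construction, since a smaller pseudocount enlarges each log2 difference and a larger one shrinks it. Values in TPM were larger than in FPKM, so the same pseudocount weighed less and more genes passed the filter. In ESM1 13381 genes passed it with TPM, against 12296 with FPKM. TPM also shifts the libraries against each other, and the share of each effect was not tested. ESM1 against Vector-2 gave 401 genes, 118 higher and 283 lower, across tables. The split of 33 higher and 2 lower in ESM1 became 60 and 22 with TPM and 26 and 5 with length and GC bins subtracted.

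Correlations counted as moved when they shifted by 0.1 or more. ESM1 with ESM1-NLS gave 0.390 with ESM1 kept in and 0.0807 with length and GC bins subtracted. ESM1 with ESM1-NES gave 0.398 with a mean of 5 or more, 0.413 with ESM1 kept in and 0.0747 with the bins subtracted, and ESM1-NLS with ESM1-NES gave 0.489 with the bins subtracted. One gene with a very large difference raises r by construction, and the cause of the other shifts was not tested.

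The medians of all lists with 5 or more measured members in these comparisons, 92 in all, were recomputed 746 times. Of these, 700 kept their side of the limit, 15 no longer stood apart, 21 newly did with the sign of the median unchanged, and 10 changed sign and stood apart before or after. Stemness genes in ESM1 stood apart at 0.17 with Vector-2 as the control, from which Vector-1 itself lay at 0.13. With random lists matched on length and GC content as well they did not, at percentile 95.86. With the same control, proliferation genes in ESM1 went to 0.34, unfolded protein response and ATF4 targets to -0.055, p53 targets to -0.26, immediate early genes to -0.28 and cytosolic ribosomal protein genes to -0.29, all against the main direction, and mesenchymal genes went to 0.17 and angiogenic factors to -0.36. Interferon-stimulated genes in ESM1-NLS against ESM1-NES went to -0.12 with a mean of 5 or more and -0.041 with the mean of the list. Proliferation genes in ESM1-NLS against ESM1-NES were at 0.00037 with TPM, which moves the median gene by 0.13, and the list still lay at the low end, at percentile 0.53. The cause was not tested for the others. Named genes past 1.5-fold changed sign in 0 of 312 values recomputed with a pseudocount of 0.1 or 5 or rescaled to a median of 0. That outcome was fixed in advance, so it is no check of direction. A pseudocount cannot change which of 2 values is higher. The rescaling factors, from 0.968 to 1, are too near 1 to reverse a 1.5-fold difference. Vector-2 as control was not among those settings. CDKN1A, at 97.2 FPKM in ESM1 and 45.6 FPKM in Vector-1, was at 196 FPKM in Vector-2, so its direction turns with that control. No paired analysis was possible because each group holds 1 library. At these depths, genes near 1 FPKM such as SOX2, POU5F1 and AXIN2 have wide counting intervals, and small differences in them were not detectable.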

Other observations

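Markers of other cell types were low. Of the endothelial list 2 genes were measured, EGFL7 and ESAM, with medians of -0.10 in ESM1, 0.37 in ESM1-NLS, 0.62 in ESM1-NES and -0.24 in ESM1-NLS against ESM1-NES, and EGFL7 was at 7.92 FPKM in ESM1-NES against 4.38 FPKM in Vector-2. Fibroblast and smooth muscle markers had medians of 0.21, 0.25, 0.29 and -0.12 in the same order, over 4 or 5 genes, and ACTA2 was at 4.19 FPKM in ESM1 against 1.90 FPKM in Vector-1. Leukocyte markers had medians of -0.06, 0.44, 0.39 and 0.50 over 1 to 3 genes, with CD68 at 2.22 FPKM in ESM1-NLS. Kidney packaging cell markers had medians of 0.07, 0.09, 0.03 and 0.04 over 4 to 6 genes, and PAX8 was at 2.48 FPKM in ESM1-NLS against 2.17 FPKM in Vector-2.

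The authors' deposited table gives a PPEE of 0.05 or less to 120 genes for ESM1-NLS, of which 36 have a fold change above 1 and 84 below 1. For ESM1-NES the authors' deposited table gives such a score to 20 genes above and 96 below 1. In the authors' deposited table the lower genes for ESM1-NLS had a median effective length of 11620 bases and the higher ones 1794 bases, and for ESM1-NES 5397 and 2160 bases. CTNNB1 has a fold change of 0.994 and a PPEE of 0.9999 for ESM1-NLS in the authors' deposited table, and AXIN2 one of 1.10 and 0.999. For ESM1-NES the authors' deposited table gives CTNNB1 a fold change of 0.961 and a PPEE of 0.9998. AHNAK has a fold change of 0.471 for ESM1-NLS in the authors' deposited table and MKI67 one of 0.521, both with a PPEE below 0.05. For ESM1-NES, where AHNAK was chosen after its values were seen, the authors' deposited table gives 0.549 and 0.705. The PPEE there is 0.0483 for AHNAK and 0.983 for MKI67, so MKI67 is not among the 96 lower genes.

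The patterns weighed next were found in these data, and all of their tests were chosen after the data had been seen. For GC content, loss of long RNA, and the length and GC trends the bounds were written before the value of the test was known, though after the overall trend with length had been seen. For the others they were written after.

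Long genes were lower in ESM1-NES. The effective length used for FPKM does not account for it, since on reads per library total genes over 8000 bases still lay -0.66 from those under 1000 bases. GC content does not either, because the median over 5 classes of GC content of the rho between length and difference was -0.69. Loss of long RNA in the library remains a candidate explanation. The rho was -0.56 or lower in each of 5 classes of expression. Any cause that acts by length would give the same, so that test does not single out loss of RNA. An effect of the form with the NES cannot be told apart from such a loss with 1 ESM1-NES library.

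p53 targets were higher in ESM1 than in Vector-1. The length and GC trends do not account for it, since the median of the list was 0.59 before and 0.50 after the median of each length and GC bin was subtracted. The higher of the medians in the tagged forms was 0.17. Those forms were set against Vector-2, in which this list was already higher than in Vector-1. A rise of like size need not appear from that baseline, so the value does not decide on an effect shared by any form of ESM1. The state of the Vector-1 culture cannot be told apart from an effect of ESM1, because ESM1 lay -0.26 from Vector-2 in the same list and Vector-1 lay -0.68, in a separate experiment and table. The hypothesis that ESM1 raises p53 targets may be checked with further Vector-1 and ESM1 cultures.

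Near-identical genes had opposite differences. For SMN1 and SMN2 reads divided differently between the copies are a candidate explanation, since the summed FPKM of the pair differed by at most 0.055 on the log2 scale in any comparison with a vector while SMN2 alone was at -3.78 in both tagged forms. For BAGE4 and BAGE5 the summed value differed by up to 0.53, in ESM1, between the bounds set for the test over all comparisons, so the test decides nothing. In ESM1-NLS and ESM1-NES the sum differed by -0.12 and -0.14, while BAGE4 alone was at 1.74 and 1.72. Reads divided differently between these copies are thus a candidate explanation in the tagged forms. No biological explanation was tested for these pairs.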
